A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

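The data came from a single deposited table with 6259 rows and 6 columns of values. Per the labels, each column compared the treated cells (channel 2) with control cells of the same strain (channel 1) on 2-colour arrays. It was the authors' average over 6 arrays, 3 biological replicates in each dye orientation, or over 5 arrays (3 and 2) for ATP1-111. The deposited values were linear ratios, above 0 with column medians near 1. Per the labels' protocols, total RNA was extracted with acid phenol, and cDNA primed with oligo(dT) was coupled to Cy3 or Cy5 through aminoallyl groups. The scanner, the background correction, the array normalization and the kind of average were not given in the sources used here. The direction was read from the sample titles, treated over control, and the NAR1 row was far below 1 in the NAR1 column alone. Only ratios were used, so neither spot brightness nor a filter on dim spots entered, and weak spots could not be told from bright ones. A ratio averaged over arrays by the authors hides how far the replicates lay apart. A ratio within an array shows change relative to the other transcripts.

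Each sample was its own group, with WT at 3, 11, 19 and 27 h, ATP1-111 at 27 h and NAR1 repression at 27 h. Whether the WT time points shared a control RNA was not given in the sources used here. Noise in a shared control would raise the correlation among WT columns and shift their level but not the slope. It would also stay out of the scatter of the WT points about a line, the spread used by the tests. Tests of ATP1-111 and NAR1 would then be too lenient. A shared control could not match every time point, so changes with culture age would enter the slope. The 28 control rows were left out, 14 named 3XSSC and 14 with 7 names of non-yeast genes. Ratios were taken to log2, and the 26 spots of 13 genes with 2 spots were averaged, which gave 6205 reading frames. Of these, 5705 matched a locus tag of the reference gene table (assembly R64) and took its symbol, while 500 kept their systematic name. Apart from gene order and frame length, no coordinates were used. Values in all 6 columns were required for tests, which left 6151 genes.

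The design, the alternatives, 35 gene lists and the rule for naming genes were fixed before the data were examined. The main model, in limma 3.58.1 (R 4.3.3), was a single fit over the 6 columns with a WT level at 27 h, a WT slope in hours, an ATP1-111 level and a NAR1 level. The residual spread came from the 4 WT points about their line (2 residual degrees of freedom, moderated by eBayes with 3.35 prior degrees of freedom). A curved time course therefore counts as noise, and ATP1-111 and NAR1 repression were tested only by assuming that they vary as the WT points do. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. They treat columns as samples, and the spread between the authors' replicates does not enter. The contrasts were the slope, the NAR1 level and ATP1-111 minus the fitted WT level at 27 h. The ATP1-111 level against no change and NAR1 minus the fitted WT level were added after the data were seen. Fitted changes with time are given over 24 h. Genes were also counted by size, at least 2-fold in either direction. Correlations across genes are Pearson's r, with the number of shared 2-fold genes set against the product of both list lengths over the genes in both columns.

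For each gene list the median log2 ratio was compared with 10000 random lists of the same size from the same column. These were not matched on expression since none was available. They also ignore that list members can move together, so a small shared shift can lie beyond all of them. The WT slope was tested with camera at a preset correlation of 0.01 and with an estimated one. This covered the 34 lists with at least 5 measured members, and p-values were adjusted over these lists. With an estimated correlation the test rests on the 2 residual degrees of freedom and has little power, so not passing it says little. The preset of 0.01 makes p-values too small where members move together more than that. The list of mtDNA-encoded genes had no rows, and 704 of 715 list members had a row. Counts adjusted over the list alone used the same p-values with the adjustment over the members.

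The named genes were, by the rule fixed beforehand, the 10 highest and 10 lowest at 27 h among genes past the WT slope test in that direction, the 10 highest and lowest past the NAR1 test, and the 10 largest differences in either direction past the ATP1-111 test. They also included the 10 genes with the largest smaller absolute value of WT 27 h and NAR1 repression with the same sign, up to 4 members of each list with the largest absolute values, and NAR1, ATP1 and CIT2. Members of lists named beyond these, genes behind counts of 5 or fewer, and other genes named in the closing section were chosen after their values were seen. A gene that the rule would name is not reported here.

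Alternatives were log2 hours, columns centred on their medians, columns centred and scaled to the spread of the WT 27 h column, robust eBayes, ordinary least squares, a threshold of 0.1, genes with missing values, each spot on its own, and each WT column left out in turn. For counts by size they were 1.5-fold, 3-fold, centring, and scaling to the mean spread of the columns. Spread here is the median absolute deviation. For correlations they were Spearman's rho, leaving out the 1% most extreme genes, leaving out the iron, galactose and ribosomal protein lists, single spots, and WT 19 h in place of 27 h. For lists they were means, medians without the most extreme member, centred columns and the estimated correlation. Alternatives chosen after the data were seen left out long unnamed reading frames of the length of Ty elements, frames not in the reference table, or the galactose list. A count was called unchanged within a factor of 1.5, and a correlation within the central 95% of 1000 bootstrap draws over genes.

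The fit was tested on simulated data for 6151 genes with 200 changed genes. For the WT slope it recovered 0, 16, 92 and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 2 false calls. For the NAR1 level it recovered 2, 76, 98 and 100% with 6 false calls, and for ATP1-111 minus WT 4, 30, 98 and 100% with 6 false calls. The simulated noise was normal, independent between genes and equal across the 6 columns, and changes with time were straight lines. These rates hold under those assumptions and are not error rates for the measured columns. The list percentile was tested on 100 simulated lists of 20 genes for each size of shift, and 9, 50, 100 and 100 lists lay outside the central 95% for shifts of 0, 0.25, 0.5 and 1. The other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.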

Results

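Transcript levels were measured in budding yeast (Saccharomyces cerevisiae) after loss of the mitochondrial genome (mtDNA) or after shutting off NAR1, an essential gene of cytosolic iron-sulfur cluster assembly. Cells growing in YEPD, a rich glucose medium, lost mtDNA through 6 h in 30 µg/ml ethidium bromide, a DNA-intercalating dye. RNA from these cells was compared on 2-colour arrays with RNA from cells of the same strain with intact mtDNA. The wild type (WT) was followed at 3, 11, 19 and 27 h. Cells homozygous for ATP1-111, a dominant allele of the gene for the alpha subunit of the mitochondrial ATP synthase, were measured at 27 h. In the remaining strain NAR1 expression depended on estradiol, and cells moved from 50 to 2 nM estradiol were compared after 27 h with cells kept at 50 nM. Each of the 6 conditions was given as a single ratio per gene, the authors' average over 6 arrays from 3 biological replicates in both dye orientations (5 arrays for ATP1-111). No spread between replicates came with these averages, so no value below has a replicate error of its own. Errors given with log2 changes are standard errors (SE) from a limma fit whose spread is the scatter of the 4 WT columns about a straight line in time. The number of arrays limits the precision, and across the 13 genes with 2 spots the SD of a single spot lay between 0.151 and 0.239 on the log2 scale. Values were present in all 6 columns for 6151 open reading frames, and the median ratio of a column lay between 0.958 and 1.02. The array had no rows for the mtDNA-encoded genes.

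The NAR1 transcript stood at a ratio of 0.031 after transfer to low estradiol (log2 -5.01, SE 0.107, adjusted p = 0.000104). In WT cells after mtDNA loss the NAR1 ratio was 1.42 at 3 h and 2.25 at 27 h, a slope that did not pass the test (adjusted p = 0.0593), and in ATP1-111 cells it was 0.979. The ATP1 transcript had a log2 ratio of -0.33 in WT and -0.12 in ATP1-111 cells at 27 h.

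The first question was how expression changed with time once WT cells had lost mtDNA. Of 26 tested members of the iron regulon, the Aft1 and Aft2 targets that take up and mobilise iron, 17 rose over the time course and 9 did not pass (limma's camera test of the list, adjusted p = 4.36e-14, and adjusted p = 0.606 with an estimated correlation). FIT3, a cell wall mannoprotein that retains siderophore-bound iron, reached a ratio of 96.8 at 27 h from 2.11 at 3 h (fitted log2 change over 24 h 5.20, SE 0.71, adjusted p = 0.0256). The siderophore transporter genes ARN2, ARN1, SIT1 and ENB1 reached ratios of 74.1, 43.1, 16.6 and 14.4, and FIT1 reached 26.0. The lowest genes among those that fell included CYT1 (cytochrome c1) at a ratio of 0.199 and ERG5 (a sterol desaturase) at 0.195. They also included HEM15 (ferrochelatase) at 0.234 and ELO1 (a fatty acid elongase) at 0.239. In all, 285 genes rose and 161 fell with time among the 6151 tested.

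The other genes with the highest 27 h values among those that rose were TIR4 (ratio 38.2), a cell wall mannoprotein of anaerobic cells, HSP26 (17.8), a small heat shock protein, AUS1 (15.4), a sterol uptake transporter, and HES1 (13.6), an oxysterol-binding protein. HSP26 started below the control, at a ratio of 0.298 at 3 h. The other lowest genes among those that fell were MTC7 (0.188), BTN2 (0.211), BAT1 (0.224), MYG1 (0.233), GLT1 (0.234) and the unnamed frame YBR089W (0.249). BAT1 encodes the mitochondrial branched-chain aminotransferase and GLT1 encodes glutamate synthase, an iron-sulfur enzyme. CIT2, the peroxisomal citrate synthase used as a reporter of retrograde signalling, went from a ratio of 1.00 at 3 h to 4.40 at 27 h and rose (log2 change 2.01, SE 0.28, adjusted p = 0.0262).

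These calls rest on 2 residual degrees of freedom, and without moderation of the spread no gene passed (0 rose and 0 fell by ordinary least squares, against 516 and 624 at an unadjusted p under 0.05, where limma gave 857 and 998). Left out in turn, the 3, 11, 19 and 27 h columns gave 119, 218, 0 and 53 rising and 22, 96, 0 and 17 falling genes (706 and 725 at an unadjusted p under 0.05 in limma without 19 h), columns scaled to equal spread gave 0 and 0 (692 and 443 unadjusted), and log2 hours gave 276 and 269.

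By size alone, 23 genes were at least 2-fold higher and 57 at least 2-fold lower at 3 h, 77 and 41 at 11 h, 234 and 112 at 19 h, and 318 and 175 at 27 h. With columns centred and scaled to a common spread the counts were 78 and 103 at 3 h, 104 and 58 at 11 h, 172 and 62 at 19 h, and 215 and 60 at 27 h. In these counts the number of lower genes did not grow with time. Such scaling removes growth of the spread itself (median absolute deviation 0.149 at 3 h and 0.280 at 27 h). It therefore cannot decide whether the response grew.

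Adjusted over the list alone, 21 iron regulon members rose and 0 fell, and the median ratio of the list on the log2 scale went from 0.40 at 3 h to 2.03 at 27 h. In arginine synthesis 6 of 9 genes rose (6 adjusted over the list alone), among them CPA1, ARG1 and ARG3 with log2 ratios of 2.75, 2.44 and 1.76 at 27 h. The list passed the test of the slope (camera adjusted p = 7.14e-07, and adjusted p = 0.606 with an estimated correlation). Among hypoxic and anaerobic genes 5 of 17 rose and 0 fell (7 and 0 adjusted over the list alone), led by TIR4, AUS1, DAN1 (log2 ratio 3.77) and TIR1 (3.65). The median of this list at 27 h was 0.18 (camera adjusted p = 0.00693, and adjusted p = 0.606 with an estimated correlation). The drug resistance targets of Pdr1 and Pdr3 had a median of 0.99 at 27 h, with 3 of 16 genes past the slope test (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.00456, and adjusted p = 0.634 with an estimated correlation). The retrograde targets had a median of 0.75, and 2 of 8, CIT2 and DLD3, rose (3 adjusted over the list alone, camera adjusted p = 0.016, and adjusted p = 0.606 with an estimated correlation).

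**Figure D1:**
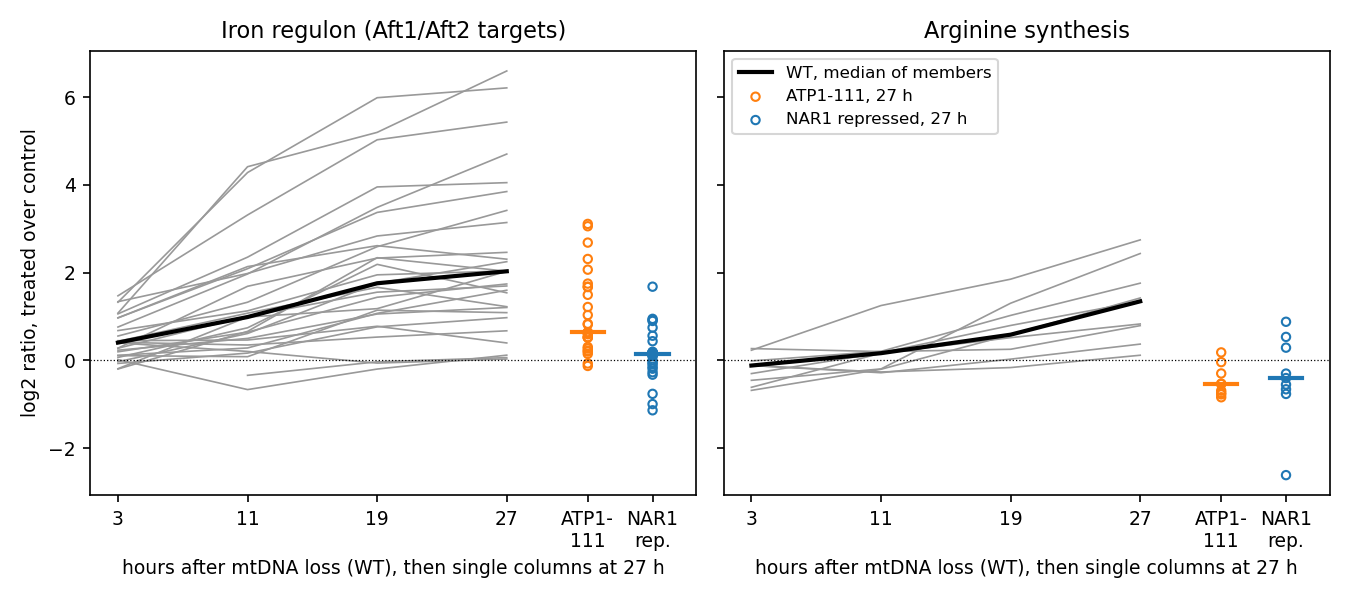
Log2 ratios (vertical axis) of the members of the iron regulon and of the arginine synthesis genes against hours after mtDNA loss in WT cells (grey lines, 1 per gene; black line, median), with the ATP1-111 and NAR1-repressed columns at 27 h as open circles and their medians as bars. The iron regulon median goes from 0.40 to 2.03 in WT and is 0.64 in ATP1-111 and 0.14 after NAR1 repression.

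Of 36 nuclear-encoded respiratory chain and ATP synthase genes 7 fell and 0 rose (13 and 0 adjusted over the list alone), among them CYT1, COX4 and QCR2 at log2 ratios of -2.33, -1.96 and -1.81. At 3 h their median was already -0.40, with 36 of 36 members below 0. It was -0.73 at 27 h (camera adjusted p = 0.00108, and adjusted p = 0.634 with an estimated correlation). Genes for iron-sulfur proteins had a median of -0.70. Of these 23 genes, 7 fell and 0 rose (15 and 1 adjusted over the list alone), among them GLT1 (-2.10) and the dihydroxyacid dehydratase gene ILV3 (-1.98) (camera adjusted p = 3.68e-05, and adjusted p = 0.606 with an estimated correlation). LEU1, the lowest member at -3.13, had an adjusted p of 0.0571. In ergosterol synthesis 9 of 21 genes fell (10 adjusted over the list alone), with ERG5, ERG11 and ERG7 at -2.36, -1.85 and -1.53 (camera adjusted p = 0.00135, and adjusted p = 0.606 with an estimated correlation). The cytosolic ribosomal protein genes had a median of -0.63 at 27 h and 0.15 at 3 h. Of these 136 genes 6 fell (83 down and 1 up adjusted over the list alone, camera adjusted p = 6.21e-19, and adjusted p = 0.606 with an estimated correlation). The G1/S and G2/M cell cycle lists each had 3 genes that fell (5 and 6 adjusted over the list alone), CLN2 reaching -1.90, CLB2 -1.51 and CLB1 -1.48 (camera adjusted p = 0.00175 and 0.0133, and adjusted p = 0.606 for both with an estimated correlation). Medians went from -0.35 at 3 h to -0.67 at 27 h for G1/S, and from -0.25 to -0.58 for G2/M. Leucine, isoleucine and valine synthesis had a median of -0.68 with 2 genes falling and 1 rising of 12 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0133, and adjusted p = 0.606 with an estimated correlation). Glycolysis and fermentation had a median of -0.53 with 0 of 19 genes past the slope test in limma (12 down and 2 up adjusted over the list alone, camera adjusted p = 0.0118, and adjusted p = 0.606 with an estimated correlation). Ribosome biogenesis genes fell with time by the camera test although their medians stayed above 0. The medians were 0.51, 0.44, 0.07 and 0.28 at 3, 11, 19 and 27 h, lowest at 19 h and not a steady decline. Of these 37 genes 0 passed singly in limma (0 adjusted over the list alone, camera adjusted p = 0.000334, and adjusted p = 0.634 with an estimated correlation).

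With columns scaled to equal spread, the median fitted change went from -0.42 to -0.11 for the respiratory chain, from -0.47 to -0.07 for G1/S, from -0.39 to -0.74 for ribosome biogenesis, from 0.53 to 0.91 for the stress response and from 0.58 to 0.24 for the mating list.

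Of the 34 lists, 11 rose and 9 fell by camera with the preset correlation of 0.01, and 0 and 0 did so with an estimated correlation. The estimated version has little power with 2 residual degrees of freedom, so its lack of calls does not decide. Estimated correlations included 0.337 for the iron regulon and 0.759 for cytosolic ribosomal proteins, so preset p-values for such lists are likely too small. The remaining lists that passed upward moved little or on few genes. Environmental stress response genes had 3 risen and 1 fallen of 24 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0148, and adjusted p = 0.682 with an estimated correlation), with HSP26 and YGP1 (2.94) up and SOD2, the mitochondrial superoxide dismutase, at -1.51. DNA damage response genes had 3 risen of 15 (6 adjusted over the list alone), among them RAD16 (1.47) and DIN7 (1.33) (camera adjusted p = 0.00693, and adjusted p = 0.606 with an estimated correlation). Glyoxylate, gluconeogenesis and beta-oxidation genes had 2 risen of 14 (4 adjusted over the list alone), PCK1 reaching 1.90 (camera adjusted p = 0.00693, and adjusted p = 0.606 with an estimated correlation). In biotin synthesis and uptake BIO5 (3.69) and VHT1 (1.60) rose, 2 of 5 (2 up and 1 down adjusted over the list alone), while BIO2, itself an iron-sulfur enzyme, was at -1.70 without passing (camera adjusted p = 0.0493, and adjusted p = 0.606 with an estimated correlation). The haploid and mating list had 1 risen of 17 (5 adjusted over the list alone, camera adjusted p = 0.0119, and adjusted p = 0.606 with an estimated correlation), and the mitochondrial ribosome list 1 of 67 (0 adjusted over the list alone), with a median of -0.00 at 27 h although the test was upward (camera adjusted p = 0.0334, and adjusted p = 0.835 with an estimated correlation). Mitochondrial iron-sulfur cluster assembly genes went both ways, with ISU1 (2.03) and MRS4 (0.97) up and YFH1 (-1.32) and GRX5 (-1.24) among 3 down (camera adjusted p = 0.244). TCA cycle genes had a median of -0.43 at 3 h and -0.50 at 27 h. The median of their fitted changes was -0.13, or 0.27 with columns scaled to equal spread (camera adjusted p = 0.722).

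**Figure D2:**
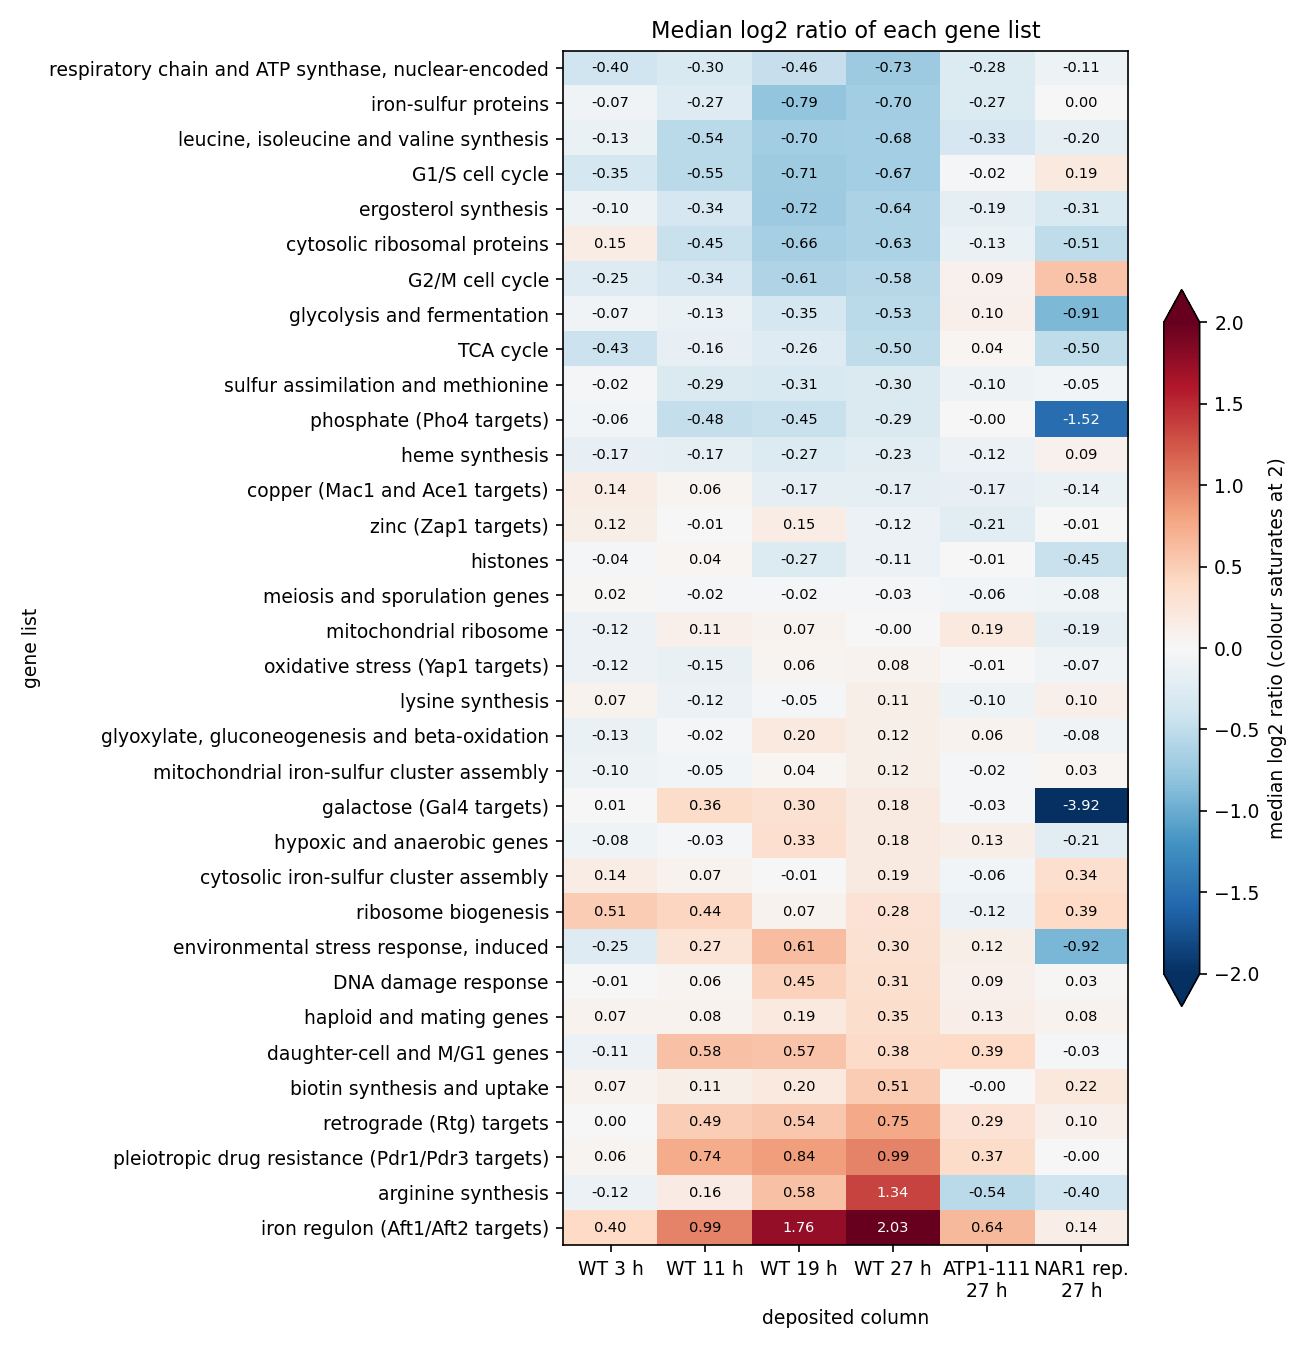
Median log2 ratio of each of 34 gene lists (rows, ordered by WT at 27 h) in the 6 deposited columns. The number in each cell is the median, and the colour scale saturates at 2. The iron regulon stands highest at WT 27 h (2.03) and the galactose list lowest after NAR1 repression (-3.92).

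The next question was whether ATP1-111 changed the response to mtDNA loss. At 27 h 13 of 26 iron regulon members were lower in ATP1-111 than in WT cells and 0 were higher (20 lower and 1 higher adjusted over the list alone). FIT3 had a ratio of 8.32 against 96.8 in WT, ARN1 6.43 against 43.1 and FIT1 3.20 against 26.0 (ATP1-111 minus fitted WT on the log2 scale for FIT1 -3.05, SE 0.156, adjusted p = 0.0102). Arginine synthesis genes were lower in 6 of 9 cases (8 adjusted over the list alone), and ARG1 lay below 1 in ATP1-111 (ratio 0.558) and above it in WT (5.41). Respiratory chain genes were higher in ATP1-111 for 10 of 36 members and lower for 0 (16 and 0 adjusted over the list alone), with CYT1 at a ratio of 0.544 against 0.199. Over all genes, 190 were higher and 284 lower in ATP1-111 than in WT.

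The genes furthest below WT also included AUS1 (ratio 1.30 against 15.4), PRY1 (1.31 against 11.9), HXT2, a glucose transporter (0.871 against 8.09), YHK8 (0.997 against 8.03) and YOR338W (1.71 against 12.1). Those furthest above WT included MTC7 (0.793 against 0.188), MET6, the methionine synthase (0.891 against 0.223), ERG5 (0.753 against 0.195), CLN2, a G1 cyclin (0.844 against 0.268), COR1 (0.782 against 0.258), YHB1, a flavohaemoglobin (1.00 against 0.331), ADE17 (1.06 against 0.313), YBR089W (0.803 against 0.249) and SFG1 (1.14 against 0.379). RRG1 and YLR366W were far from 1 in ATP1-111 alone. RRG1 had a ratio of 0.032 in ATP1-111 and 1.08 in WT, and YLR366W 5.40 and 0.946. CIT2 had a ratio of 1.18 in ATP1-111 against 4.40 in WT (log2 difference from the fitted WT level -1.99, SE 0.27). The retrograde list as a whole was still raised in ATP1-111. Its median was 0.29 against 0.75 in WT, with 7 of 8 members above 0 and 3 at least 2-fold higher in ATP1-111. Ergosterol synthesis genes were higher in ATP1-111 for 8 of 21 members (10 adjusted over the list alone), ribosomal protein genes for 7 of 136 (0 adjusted over the list alone), and the G1/S and G2/M lists for 5 members each (14 and 7 adjusted over the list alone).

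In the ATP1-111 column itself 43 genes were at least 2-fold higher and 23 at least 2-fold lower, and 4 and 3 passed limma's test against no change (225 and 274 at an unadjusted p under 0.05). The higher genes were FIT1, FRE2, FET3 and YLR366W, and the lower ones RRG1, VPS30 and YHR139C-A. The iron regulon median was 0.64, above all 10000 random lists of its size, of which the highest was 0.19. The Pdr1 and Pdr3 targets had a median of 0.37, also above all random lists. The mitochondrial ribosome list had a median of 0.19 in ATP1-111, also above all random lists, and the daughter-cell and M/G1 list a median of 0.39. Mitochondrial ribosome genes moved together (estimated correlation 0.763 in the WT fit), which random lists ignore, so little weight rests on that rank. Lists below all random lists included arginine synthesis (-0.54) and leucine, isoleucine and valine synthesis (-0.33). They also included the respiratory chain (-0.28) and genes for iron-sulfur proteins (-0.27).

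Each ATP1-111 value was tested as if it varied like the WT columns about their line, and the counts of higher and lower genes moved to 367 and 465, 93 and 176, 0 and 0, and 23 and 61 without the 3, 11, 19 or 27 h column (678 and 749 at an unadjusted p under 0.05 in limma without 19 h), to 42 and 95 with log2 hours, and to 0 and 0 by ordinary least squares (632 and 549 unadjusted). The ATP1-111 column had the smallest spread over genes (SD 0.27 against 0.63 in WT at 27 h), and with columns scaled to equal spread 5 genes were higher and 26 lower, the median iron regulon difference went from -1.23 to -0.08 and that of the respiratory chain from 0.54 to 0.15, FIT3 and ARN1 changed sign (0.19 and 0.48), and the median retrograde target difference went from -0.36 to 0.14, while the median differences of arginine synthesis (-2.03 to -3.01), G1/S (0.70 to 0.71), G2/M (0.71 to 0.80) and ergosterol synthesis (0.57 to 0.46) kept their sign.

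A further comparison asked how expression changed after NAR1 repression in cells with intact mtDNA. Estradiol was lower in the repressed cells, so effects of the dose and of NAR1 loss cannot be told apart in this column. Genes of galactose use, the targets of Gal4, fell most: GAL7, GAL1, GAL2 and GAL10 had ratios of 0.014, 0.017, 0.019 and 0.027, and 8 of the 9 listed genes were lower (9 adjusted over the list alone). Phosphate genes under Pho4 were lower in 9 of 12 cases (10 adjusted over the list alone), among them the transporter gene PHO84 (ratio 0.109). Stress response genes were lower in 15 of 24 cases and higher in 0 (19 and 1 adjusted over the list alone), with CTT1, the cytosolic catalase, at 0.089. By size, 10 members of this list were at least 2-fold lower and 2 at least 2-fold higher, led by HSP26 (ratio 6.32), which did not pass. The iron regulon had a median log2 ratio of 0.14, with 4 members higher and 3 lower of 26 (5 and 3 adjusted over the list alone). Over all genes 819 were higher and 686 lower.

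The highest genes past the test were NCA3 (ratio 8.85, log2 3.15, SE 0.105, adjusted p = 0.000434), YOR338W (5.98), KTR2, a mannosyltransferase (5.53), GIC2, a Cdc42 effector (5.06), PLB3, a phospholipase B (4.99), PRY2 (4.65), ARO10 (4.57), YPS3, a cell surface aspartic protease (4.23), MIG2, a glucose repressor (4.17) and SVS1 (4.10). MIG2 passed narrowly (adjusted p = 0.0498). The lowest after the galactose genes and NAR1 were PGM2, a phosphoglucomutase that was on both the galactose and the stress list (0.066), CTT1, PHO84, ADH6, an alcohol dehydrogenase (0.109) and GSY1, a glycogen synthase (0.112).

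Glycolysis and fermentation genes were lower in 11 of 19 cases (15 adjusted over the list alone), with ADH1, PGK1 and ENO1 at log2 ratios of -1.72, -1.52 and -1.36, and the list median of -0.91 lay below all 10000 random lists. Cytosolic ribosomal protein genes were lower in 37 cases and higher in 1 of 136 (52 and 1 adjusted over the list alone), the lowest being RPL18B (-2.02). TCA cycle genes were lower in 7 of 15 cases (9 adjusted over the list alone), among them MDH1 (-1.53), FUM1 (-1.03) and ACO1 (-1.01). Ribosome biogenesis genes were higher in 10 and lower in 2 of 37 cases (18 and 3 adjusted over the list alone), and G2/M genes were higher in 6 of 11 (6 adjusted over the list alone), among them CLB2 (1.04) and CDC20 (0.72). CLN2, which fell in WT after mtDNA loss, was higher here (1.16, adjusted p = 0.00663). Within the iron regulon ISU2 (1.68) and FRE6 (0.95) were higher and CCC2 (-1.14) was among those lower. Among cytosolic iron-sulfur assembly genes other than NAR1, DRE2 (1.15) and CIA2 (0.50) were higher. Among genes for iron-sulfur proteins 6 were higher and 3 lower of 23 (6 and 3 adjusted over the list alone), with GRX4 at 1.04 and RLI1 at 0.95. Ergosterol synthesis was lower in 6 and higher in 1 of 21 cases (7 and 2 adjusted over the list alone), ERG6 reaching -1.31. ARG4 was at -2.62, where 4 of 9 arginine synthesis genes were lower and 1 higher (4 and 2 adjusted over the list alone).

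By size, 135 genes were at least 2-fold higher and 229 at least 2-fold lower after NAR1 repression, or 39 and 119 with columns centred and scaled to a common spread. The NAR1 column was tested like ATP1-111, on the scatter of the WT columns, and the counts of 819 and 686 became 534 and 526 without the 11 h column, 432 and 411 without 19 h, 61 and 117 with columns scaled to equal spread, and 0 and 0 by ordinary least squares (997 and 749 at an unadjusted p under 0.05, where limma gave 1375 and 1140).

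The last comparison set the responses side by side across genes, which are not independent replicates. NCA3 was high after both treatments, with ratios of 8.77 in WT 27 h after mtDNA loss and 8.85 after NAR1 repression. HSP26 (17.8 and 6.32), YOR338W (12.1 and 5.98), MIG2 (5.20 and 4.17), YPS3 (3.28 and 4.23), YRO2 (3.96 and 3.22), PRM5 (2.86 and 2.94), PRY1 (11.9 and 2.80), KTR2 (2.76 and 5.53) and PHM8 (2.61 and 2.79) were the other genes furthest from 1 in the same direction in both columns. HSP26 did not pass the NAR1 test (adjusted p = 0.058), and MIG2, PRM5 and KTR2 did not pass the WT slope test.

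Over all genes Pearson's r was 0.187 between WT at 27 h and NAR1 repression, 0.468 between WT and ATP1-111 at 27 h, and 0.087 between ATP1-111 and NAR1 repression. Of the 318 genes at least 2-fold higher in WT, 46 were also at least 2-fold higher after NAR1 repression, where independent lists would share 6.93. Without the long unnamed frames of Ty length, an alternative chosen after seeing the data, 34 were shared, against 6.07. For lower genes the overlap was 15, against 6.47, and 23 genes were higher in WT and lower after NAR1 repression, against 11.8. The reverse, lower in WT and higher after NAR1 repression, held for 9 genes, against 3.82. Between WT and ATP1-111 the shared genes numbered 28 higher, against 2.21, and 3 lower (LEU1, BIO2 and BAT1), against 0.648. ATP1-111 and NAR1 repression shared 0 higher and 0 lower genes, against 0.94 and 0.853. BDH2, PDR15, PTR2 and ACO1 were higher in ATP1-111 and lower after NAR1 repression (4 genes, against 1.59). COS12 showed the reverse (1 gene, against 0.503). A test of NAR1 repression minus the fitted WT level at 27 h, added after the data were seen, called 856 genes higher and 744 lower, the iron regulon genes FIT3, ARN1, ARN2, FIT1, SIT1 and ENB1 among the lower. With WT at 19 h in place of 27 h, the correlation with NAR1 repression was 0.087.

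**Figure D3:**
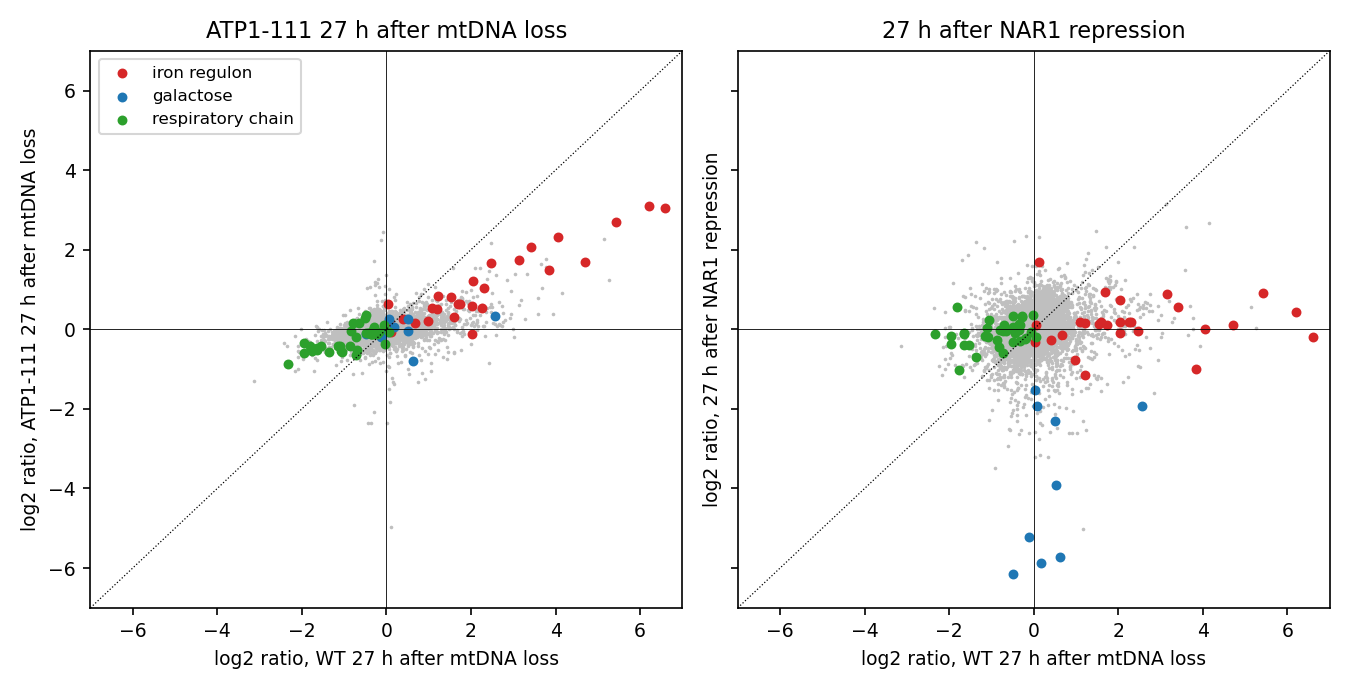
Log2 ratio of each gene in WT 27 h after mtDNA loss (horizontal axis) against ATP1-111 27 h after mtDNA loss (left) and 27 h after NAR1 repression (right). Grey points are genes, coloured points are members of 3 gene lists, and the dotted line marks equal values. Iron regulon members lie between the line and 0 on the left for the largest WT values, and galactose genes lie far below 0 on the right only.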

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

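All tests of explanations in this part were chosen after the results they bear on had been seen in whole or in part.

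A test of the difference between ATP1-111 and WT cells at 27 h after mtDNA loss called 190 genes higher and 284 lower in ATP1-111. ATP1-111 is a single column, tested on the scatter of the WT columns, and the counts were 0 and 0 without WT 19 h or by ordinary least squares (limma and least squares, unadjusted p under 0.05: 678 and 749, and 632 and 549), 5 and 26 with columns scaled to equal spread, 23 and 61 without WT 27 h, 93 and 176 without 11 h, 367 and 465 without 3 h, and 42 and 95 with log2 hours. By list, the members lower in ATP1-111 numbered 13 in the iron regulon and 6 in arginine synthesis, and those higher numbered 10 in the respiratory chain, 8 in ergosterol synthesis, 7 among ribosomal proteins, and 5 each in G1/S and G2/M. The named genes lower in ATP1-111 than the fitted WT level, on the log2 scale, were RRG1 (-5.31), FIT3 (-3.87), PRY1 (-3.52), AUS1 (-3.25), HXT2 (-3.17), ARN1 (-3.17), ARG1 (-3.14), FIT1 (-3.05), YHK8 (-3.02), YOR338W (-2.59), CPA1 (-2.56), ARG3 (-2.19), ARG56 (-2.09), CIT2 (-1.99) and NAR1 (-1.17). With columns scaled to equal spread, FIT3 and ARN1 changed sign (0.19 and 0.48). Those higher were YLR366W (2.54), MET6 (2.20), ERG5 (2.10), MTC7 (2.00), YBR089W (1.83), CLN2 (1.71), YHB1 (1.66), SFG1 (1.64), ADE17 (1.54), ERG11 (1.54), CYT1 (1.51), COR1 (1.48), MCD1 (1.46), QCR2 (1.40), COX4 (1.35), CLN1 (1.29), ERG7 (1.27), CLB1 (1.25), CLB2 (1.25), HST3 (1.12), RPS10A (1.03) and SWI5 (1.01).

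Of 26 iron regulon members 17 rose in WT and 13 were lower in ATP1-111 (camera test of the list in WT, adjusted p = 4.36e-14, and adjusted p = 0.606 with an estimated correlation). Of the 26 measured at both times, 24 were higher at 27 h than at 3 h. This argues against a fading effect of ethidium bromide as the cause of the rise. A fading part of the 3 h values (list median 0.40) and a delayed effect stay open. An ATP1-111 column in which every response was compressed by a common factor would leave the iron regulon with the same share as other genes. Its 21 members at least 2-fold higher in WT at 19 h kept 45.1% of their mean WT 27 h log2 ratio, against 12.6 to 33.2% for the central 95% of random sets from 213 other such genes, and 20.4 to 36.5% for sets matched incompletely on the 19 h value (mean 2.24 against 2.61). Its share lay above both ranges, but this does not settle whether 1 factor held for all genes. The median share rose from 23.1% in random to 28.4% in matched sets, whose 19 h values were still lower. The genes were also chosen on a column that may share a control with WT 27 h. As a share of its WT value, the iron regulon was reduced less than the other genes chosen. In log2 units its median difference from WT, -1.23, was further below 0 than that of any other list except arginine synthesis (-2.03). A weakening by a common share would lower the highest lists most. The iron regulon was the highest list in WT (median 2.03 at 27 h), so its log2 drop cannot decide. Scaling columns to equal spread moved the iron regulon's median difference from -1.23 to -0.08 (members below 0 from 25 to 14 of 26). By share and after scaling, the values give no sign of a reduction specific to the iron regulon. For the iron regulon, a general weakening of responses in the ATP1-111 column that differs from gene to gene stays open, untested. It could come from the averaging, the unequal dye orientations of the 5 arrays or the genotype. Arginine synthesis values argue against weakening alone for those genes. Their median was 1.35 in WT at 27 h (9 of 9 above 0) and -0.54 in ATP1-111 (8 of 9 below 0). The lowest of the random lists in ATP1-111 was -0.31.

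The fall of Gal4 targets after NAR1 repression may come from the estradiol system: a lower estradiol dose would lower an estradiol-dependent activator that also drives Gal4 targets. The list median was -3.92, below the lowest of 10000 random lists (-0.77), while in WT at 27 h it was 0.18 and lay inside the central 95% of random lists. These values prompted the explanation and cannot test it, and no column lowered estradiol with NAR1 expressed, so the dose and the loss of NAR1 cannot be told apart for these genes. Of the genes on either side of NAR1 in the reference gene order, LAP3 had a log2 ratio of -2.40 and ZWF1 of -0.04, and no part of the other changes in this column was tested against the change in dose.

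In the control spots that carry names of non-yeast genes, 5 of the 12 with a value had a ratio of at least 2 in the ATP1-111 column and 0 in each of the other columns. The median of the spots with a value was 1.98 in ATP1-111 and between 0.679 and 1.14 elsewhere.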

How the results depend on the processing

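The alternatives without the Ty-length frames, without frames missing from the reference table and without the galactose list were chosen after the data were seen, and kept every count of calls within 1.5 times. So did centring, robust eBayes, missing values and single spots. No paired analysis was possible because each condition is a single averaged column. Rank of time was not run, as it equals hours for evenly spaced points. In the order WT rising and falling, NAR1 higher and lower, and ATP1-111 minus WT higher and lower, the counts were 285, 161, 819, 686, 190 and 284. They were 0, 0, 61, 117, 5 and 26 with columns scaled to equal spread (limma, unadjusted p under 0.05: 692, 443, 802, 777, 547 and 686), all 0 by ordinary least squares (516, 624, 997, 749, 632 and 549 unadjusted), and 551, 554, 1264, 1037, 550 and 571 at a threshold of 0.1. Log2 hours moved WT falling to 269 and ATP1-111 minus WT to 42 and 95. Leaving out a WT column gave ranges of 0 to 218, 0 to 96, 432 to 1052, 411 to 930, 0 to 367 and 0 to 465, with the 0 counts without 19 h. The cause of these changes was not tested. At 1.5-fold and 3-fold, WT 27 h had 685 and 146 higher and 645 and 42 lower genes, ATP1-111 122 and 15 higher and 86 and 7 lower, and NAR1 597 and 24 higher and 621 and 68 lower. Scaling gave 60 lower in WT, 137 higher and 99 lower in ATP1-111, and 39 higher and 119 lower after NAR1 repression. The correlation of WT and NAR1 was 0.252 as Spearman's rho, 0.227 without the 1% most extreme genes and 0.087 with WT 19 h. That of WT and ATP1-111 was 0.364 as rho, 0.410 without extreme genes and 0.407 without the 3 lists, and that of ATP1-111 and NAR1 was 0.057 as rho. Lists rising and falling by camera numbered 0 and 0 with an estimated correlation, a version with little power here, and 10 and 9 with centred columns. Of the named genes, 2 reversed, FIT3 (0.192) and ARN1 (0.483) in ATP1-111 minus WT with scaled columns, 191 gene and setting pairs lost the call and 347 kept it. All 306 alternatives for list medians moved by less than the spread of the members, a wide margin that says little about robustness. The hypoxic list at WT 27 h had a median of 0.18 and a mean of 1.02. Scaled columns were not among these alternatives. Without spot brightness, the effect of dim spots could not be assessed.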

Other observations

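The test of repeat signal and the count of time orders in this part were chosen after the results were seen.

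Some genes were already far from 1 at 3 h. At all 4 WT times 10 genes were at least 2-fold higher, among them the iron regulon genes FET3, SIT1, ARN1, ARN2 and FIT3, and WSC4 and ADE17 were at least 2-fold lower. The adjoining frames PRM7 and YDL038C showed no trend. PRM7 had log2 ratios of 3.24, 2.12, 1.44 and 3.27 at 3, 11, 19 and 27 h, YDL038C 2.95, 2.67, 2.09 and 2.93, and in ATP1-111 they were at 0.25 and 0.29. ADE17, a purine synthesis gene, was at -1.22, -1.16, -1.04 and -1.68 in WT and 0.08 in ATP1-111. PAU5, PAU2, PAU22, SPS100 and SNO1 were at least 4-fold higher at 27 h (2.79, 2.17, 2.08, 2.15 and 2.13) and under 2-fold in every other column, while PAU18 was at -2.83 at 3 h and -0.22 at 27 h. A few genes were at least 4-fold from 1 in the ATP1-111 column and under 2-fold elsewhere: RRG1 (-4.97), HUT1 (-2.36), VPS30 (-2.34), YHR139C-A (-2.08) and YLR366W (2.43).

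Among the lists that passed no slope test, zinc genes had a median of -0.12 at WT 27 h, copper genes -0.17, histones -0.11, heme synthesis -0.23, lysine synthesis 0.11, sulfur assimilation and methionine -0.30, phosphate -0.29, oxidative stress 0.08, meiosis and sporulation -0.03, and cytosolic iron-sulfur cluster assembly 0.19. The daughter-cell and M/G1 list was at 0.38 in WT at 27 h and -0.03 after NAR1 repression. Median and mean lay on opposite sides of 0 in WT at 27 h for zinc (mean 0.17), lysine synthesis (-0.02), meiosis and sporulation (0.29) and the mitochondrial ribosome (0.01). After NAR1 repression they did so for cytosolic iron-sulfur cluster assembly (median 0.34, mean -0.24, NAR1 itself included), heme synthesis (0.09 and -0.21), retrograde targets (0.10 and -0.15) and copper genes (-0.14 and 0.09), among others. Copper metallothionein genes CUP1-1 and CUP1-2, near-identical copies, were at -0.89 and -0.89 in WT and 1.02 and 0.96 after NAR1 repression.

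The 13 unnamed frames of 5000 to 5400 bp, the length of Ty retrotransposons, moved together, with medians of 0.11, 0.52, 1.03 and 1.77 in WT, 0.71 in ATP1-111 and 1.07 after NAR1 repression. Their SD in WT at 27 h was 0.049, under the 0.239 of a single spot. This is consistent with near-identical repeats sharing a hybridisation signal, in which case they count as 1 measurement and not 13. Whether the elements themselves were transcribed more was not tested. Without them, 255 genes rose and 145 fell in WT.

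With 4 WT columns there are 12 distinct orders in time, too few for a share under 0.05. The real order called 446 genes, the highest of the others called 1, and 1 of the 12 orders, the real one, gave as many genes.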
